A study of Mus musculus with 20 samples.

How the data were processed

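Chromatin immunoprecipitation (ChIP) and RNA were measured in mouse embryonic fibroblasts of wild-type (WT) mice and of mice without PML (KO), the protein that builds PML nuclear bodies. The 20 samples comprised 12 ChIP libraries and 8 RNA samples. ChIP targets were H3, H3K9me3, H3K27me3, PML and the histone variant H3.3 with a Flag or an HA tag, with 1 library per target and genotype. Cells for H3.3 ChIP were transfected with the tagged histone, and cells for RNA were native, per the labels' protocols. RNA came as 3 numbered replicates and 1 unnumbered sample per genotype. The numbered replicates were pooled by the authors into 1 table per genotype, and 0 columns of single replicates were present in the tables used here.

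Reads were aligned to mm10, and Bowtie 1.0.0, TopHat2 2.0.8b, Cufflinks 2.2.1 and Cuffdiff 2.2.1 were named in the submitters' processing notes. The region caller was not given in the sources used here. The ChIP files deposited were lists of called regions. For H3.3, H3K9me3 and H3K27me3 each region carried a signal value and a score made by the authors. For H3 and PML the deposited value was a single score per region. The signal times the number of 1 kb bins of a region was a whole number on chromosomes 1 to 9 and X, and mostly not on chromosomes 10 to 19, so a signal minimum need not mean the same in both sets, and chromosomes 10 to 19 were also analysed alone. The RNA tables deposited by the authors held FPKM, fragments per kilobase of transcript, scaled to the mapped fragments. Read totals were not in the files used here, so the depth of every library is unknown and no limit of detection could be computed.

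Region lists were analysed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The analysed space was chromosomes 1 to 19 and X from base 3000000, 2573 Mb in all. It left out Y and the first 3 Mb of each chromosome, where some libraries held long calls and others none, and this space was settled after those calls had been seen. Regions of a pair were compared by number, covered length and overlap of at least 1 bp, where numbers and shares of regions used all regions and lengths the analysed space. Shares of regions carry 95% Wilson intervals, which treat regions as independent and cover counting error only. Overlap with PML regions, the change inside against outside PML regions and the exchange of marks were tested by rotating the WT PML regions along each chromosome in steps of 10 kb. Each test used 10000 rotations, was two-sided and was adjusted by Benjamini-Hochberg within its family of 10 libraries, 5 marks or 5 kinds of base. The smallest p these rotations can give is 0.0001. Rotation tests how regions are arranged within these libraries and not a difference between animals.

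RNA differences were KO minus WT of log2(FPKM + 1). Genes were used when their FPKM was at least 1 in either genotype. Lines that named several genes (267 or 271 per table) and repeated names were left out. Of the 22593 genes in all 4 tables, 99.5% were matched by symbol to the RefSeq annotation of GRCm38.p6, the assembly of mm10. With 1 value per genotype and table pair no replicate test was possible, so no p was computed across genes, and a difference of at least 2-fold is a description. Gene lists fixed before the data were examined were summarised by their median difference and its percentile among 10000 random lists matched on 20 bins of mean expression. Values below 2.5 or above 97.5 are called outside the random lists, as a description of these libraries.

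A gene was assigned to a region set when at least 0.5 of its length was covered, and to a gain or loss when its covered share differed by at least 0.5 between genotypes. The share of expressed genes was compared with rotated regions. For median RNA differences, rotation of the regions was the planned test. On simulated data without any shift it called 86.0% of 50 sets, because rotated regions held many more expressed genes than PML regions do. It was replaced, after the real values had been seen, by rotation of the membership along the measured genes of each chromosome, which keeps the size of the set. Percentiles among expression-matched random lists were added as a second description at the same point.

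The overlap test, the change test, the list percentiles and the membership rotation were tested on simulated data built on the real regions or genes. The exchange test and the share of expressed genes were not simulated. For the overlap test on 20732 H3K9me3 regions, 6.00% of 200 sets without a tie to PML regions were called at 0.05, and 100% of sets with one. For the change test on 20720 regions, 3.50% of 200 sets with equal loss were called, and all sets with a true difference of -0.68 were called with a median estimate of -0.64. For lists of 25 among 10390 genes, 4.50% of 200 unshifted lists lay outside the random lists, against 82.0% at a shift of 0.5 and 100% at a shift of 1. For membership rotation with 49 of 9683 genes in PML regions, the shares were 6.50%, 79.5% at a shift of 0.5 and 100% at a shift of 1.

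The genes and regions to name were set by a rule before the data were examined. For RNA it took Pml and the list of PML body and H3.3 chaperone genes, then the 10 genes highest and the 10 lowest in KO among those at FPKM of at least 5 and at least 2-fold in the same direction in both table pairs, then the 4 members of each list with the largest absolute difference, with a cap of 30 genes per comparison. Each list was treated as a comparison of its own for the cap. The wording left open in which pair the minimum applied, and it was settled after values had been seen as the pair ranked by. For ChIP the rule took the 5 longest and the 5 most gene-rich PML regions, the 5 longest regions per mark called in 1 genotype only, and list members in PML regions. Genes outside this rule are marked where they appear.

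Other settings, fixed before the data were examined, were a pseudocount of 0.1, no filter or a minimum FPKM of 5, centring on the median, the unnumbered tables, a minimum region length, the upper part of the authors' score, merging within 1 kb, autosomes only, a stricter overlap, PML regions untouched in KO, and bases outside H3 calls. Signal minima of 1 and 3 (after minima between 1 and 5 had been looked at), chromosomes 10 to 19 only and assignment by gene midpoint were added after the data had been seen.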

Results

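Chromatin and RNA of mouse embryonic fibroblasts with and without PML were profiled to ask how the loss of PML relates to H3.3 deposition and to heterochromatin marks, as the labels of the series describe. ChIP region lists covered H3, H3.3-Flag, H3.3-HA, H3K9me3, H3K27me3 and PML in WT and KO, with 1 library each. RNA was given as FPKM in 2 pairs of tables, 1 pair pooled from 3 numbered replicates per genotype and 1 pair from the unnumbered samples. No value had a replicate in the files used, so every difference between genotypes is a difference between single libraries or pooled tables. Read depth was unknown. WT libraries held 484 regions for PML, 513 for H3, 28213 for H3.3-Flag, 6730 for H3.3-HA, 20732 for H3K9me3 and 17668 for H3K27me3. KO libraries held 35, 495, 20641, 1759, 10835 and 12328 regions for the same targets. All coordinates are on mm10.

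PML regions were long domains in WT that were almost all missing in KO. The 484 WT regions had a median length of 810 kb and covered 515.5 Mb, 20.0% of the analysed genome. In KO, 13 regions lay outside Y, covering 24.2 Mb, and 13 WT regions (2.69%, 95% interval 1.58% to 4.54%) were touched by them. The domains were poor in genes, with 5.12 protein-coding genes per Mb inside against 9.23 outside, and 98 regions held none. Olfactory receptor genes, which detect odours, had 790 of 1110 members inside, and vomeronasal receptor genes, which detect pheromones, 244 of 355. Of the 53 keratin genes, the 39 Hox genes and the 57 genes of the protocadherin clusters, 0 lay inside.

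The longest PML region ran from 98250001 to 105420000 on chromosome 1, over Slco6d1, Cntnap5b, Cdh20 and Rnf152. The next lay on chromosome 1 from 112320001 to 118280000 with Cntnap5a, on chromosome 12 from 59230001 to 64880000 with Lrfn5 and Fscb, and on chromosome 8 from 95900001 to 101520000 with Cdh8. A region on chromosome 2 from 85590001 to 90380000 held 216 genes, mostly olfactory receptors, and was both the fifth longest and the most gene-rich. Olfactory receptors also filled the gene-rich regions on chromosome 9 from 37940001 to 40190000 (91 genes) and on chromosome 7 from 102690001 to 104190000 (90 genes) and from 106720001 to 108910000 (71 genes). The other gene-rich region, on chromosome 14 from 3000001 to 7720000, held 76 genes, mostly predicted ones, and was fully covered by H3 calls in both genotypes. List members inside PML regions were Pdgfra, Adgre1, Laptm5, Elavl4, Matn1 and Dppa4, the olfactory and vomeronasal receptors, 33 zinc finger genes named Zfp and 56 defensin and serpin genes.

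H3.3-Flag regions were largely shared between genotypes. They covered 286 Mb in WT and 306 Mb in KO, and 79.0% of the WT length was also called in KO. Of the WT regions, 73.7% (95% interval 73.2% to 74.2%) were touched by a KO region. The longest region called in WT alone spanned 88 kb over Sp100 and Sp140 on chromosome 1, from 85628001 to 85716000. Sp100 encodes another constituent of PML bodies. Others covered parts of Mid1, Cd2ap, Glcci1 and the imprinted gene Plagl1, on chromosome 10 from 13085001 to 13135000. Of the 5 longest regions called in KO alone, 4 held no protein-coding gene and lay wholly in PML regions, the longest on chromosome 12 from 115552001 to 115684000, and the other overlapped Dnah8.

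H3.3-HA regions differed far more, with 73.5 Mb in WT and 374.8 Mb in KO, a ratio of 5.10. In WT, 96.7% of HA regions were touched by a Flag region and 85.1% of their length was shared with Flag. In KO, 81.5% of HA regions were touched by a Flag region and 26.7% of the HA length was shared with Flag. The longest WT regions missing in KO included Morn1 and Ski, and a stretch on chromosome 4 from 156159001 to 156256000 with Agrn and the interferon-induced gene Isg15. The longest KO regions missing in WT exceeded 1 Mb, such as that over Ptprn2 and Rapgef5 on chromosome 12 from 116466001 to 117814000, with a signal of 0.322. Regions with a signal under 1 made up 222.7 of the 374.8 Mb in KO. With a minimum signal of 3 the ratio turned to 0.504, so the direction of this difference depended on faint calls.

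H3K9me3, a mark of heterochromatin, covered 840.6 Mb in WT and 735.1 Mb in KO, a ratio of 0.875. Of the WT length, 54.3% was also called in KO. The 5 longest regions called in WT alone lay wholly in PML regions and included Nrxn3 on chromosome 12 from 88552001 to 89341000, Fscb on chromosome 12 from 64207001 to 64820000 and Dpp10 on chromosome 1 from 122852001 to 123349000. The longest called in KO alone lay on chromosome 9 from 45077001 to 45780000, with Il10ra, Scn2b and Dscaml1, and 92.5% of it lay in a PML region. Others covered Kcnd3, Myo16 and the homeobox gene Otx2, on chromosome 14 from 48527001 to 48981000. Signals ran from 0.179 to 4.36 in the 5 longest WT regions and from 4.05 to 8.04 in the 5 longest KO regions. WT calls were fainter, with 534.1 of these 840.6 Mb below a signal of 3 against 1.91 Mb in KO, and with a minimum of 3 the ratio was 2.39.

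H3K27me3, the mark set by Polycomb complexes, covered 961.9 Mb in WT and 1018 Mb in KO, and 79.1% of the WT length was also called in KO. The longest regions called in WT alone overlapped Rims2 on chromosome 15 from 39150001 to 39536000, Zfhx3, Nckap5, Slit3 and Wwox. Of the 5 longest called in KO alone, 4 held no protein-coding gene, the longest on chromosome 10 from 45897001 to 46282000. These 5 were faint, with signals from 0 to 3.49, against 3.07 to 19.2 for the 5 longest called in WT alone. H3 regions covered 434 Mb in WT and 519 Mb in KO, and 76.2% of WT regions were touched in KO. H3 regions in WT alone included Dab1 on chromosome 4 from 103360001 to 104960000, Xylt1, Nrxn3, Grin2b and Pld5. H3 regions in KO alone included Jun and Tek on chromosome 4 from 92710001 to 96200000, and a stretch of X from 100370001 to 102960000 with Eda and Ogt.

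The marks were arranged about PML regions in distinct ways in WT. H3K9me3 covered 69.9% of PML regions against 34.7% (SD 1.24) after rotation, and 23.3% of the remaining genome. H3.3 was nearly absent there, with 0.203% for Flag and 0.316% for HA, against 10.6% (SD 0.486) and 2.79% (SD 0.176) after rotation. H3K27me3 covered 29.4% inside, below the 38.9% (SD 1.07) of rotations, and H3 25.5%, above 17.5% (SD 1.24). In KO, H3K9me3 covered 44.2% of the same regions, H3K27me3 53.7% and H3.3-Flag 0.452%, all apart from rotations. Each of these 8 comparisons had an adjusted p of 0.000125, with a raw p at the smallest value rotations can give. In KO, H3.3-HA covered 13.9% (permutation test by rotation, adjusted p = 0.586) and H3 17.9% (adjusted p = 0.0383).

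**Figure D1:**
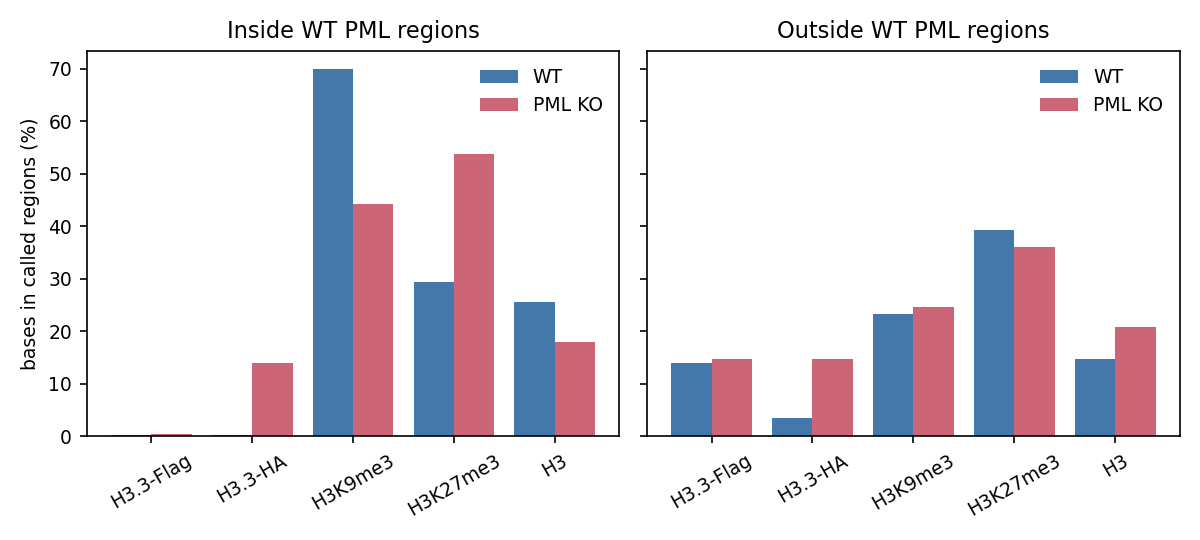
Percent of bases in called regions (vertical axis) inside and outside the WT PML regions, for each target in WT (blue) and KO (red), 1 library per bar. Over calls of any signal, H3K9me3 inside PML regions went from 69.9% in WT to 44.2% in KO and H3K27me3 from 29.4% to 53.7%.

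Over calls of any signal, PML regions held less H3K9me3 and more H3K27me3 in KO than in WT. Outside them the total lengths of all calls were close, although single chromosomes differed. With a minimum signal of 3, H3K9me3 covered 27.4% of PML regions in WT and 44.1% in KO, so its direction depended on the signal minimum. Over all calls, the log2 ratio of KO over WT covered length for H3K9me3 was -0.66 inside and 0.08 outside. For H3K27me3 it was 0.87 inside and -0.13 outside. The inside minus outside difference was -0.74 for H3K9me3 and 1.00 for H3K27me3. Without bases called in the H3 libraries, that of H3K9me3 was -0.36, with -0.80 inside and -0.44 outside. Among single regions, H3K9me3 covered less in KO in 329, more in 114 and the same share in 41 of the 484. H3K27me3 covered more in 399, less in 38 and the same in 47. These counts, and the shares of single regions below, use calls of any signal and were not computed at a signal minimum. The longest region, with Cntnap5b and Cdh20, went from 69.3% to 6.74% H3K9me3 and from 9.01% to 29.3% H3K27me3. The region of Cntnap5a went from 94.2% to 10.8% H3K9me3, that of Cdh8 from 65.5% to 6.39%, and that of Lrfn5 from 36.8% to 0.496%. The olfactory receptor region on chromosome 2 went from 68.7% to 10.3% H3K9me3 and from 7.95% to 20.4% H3K27me3.

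**Figure D2:**
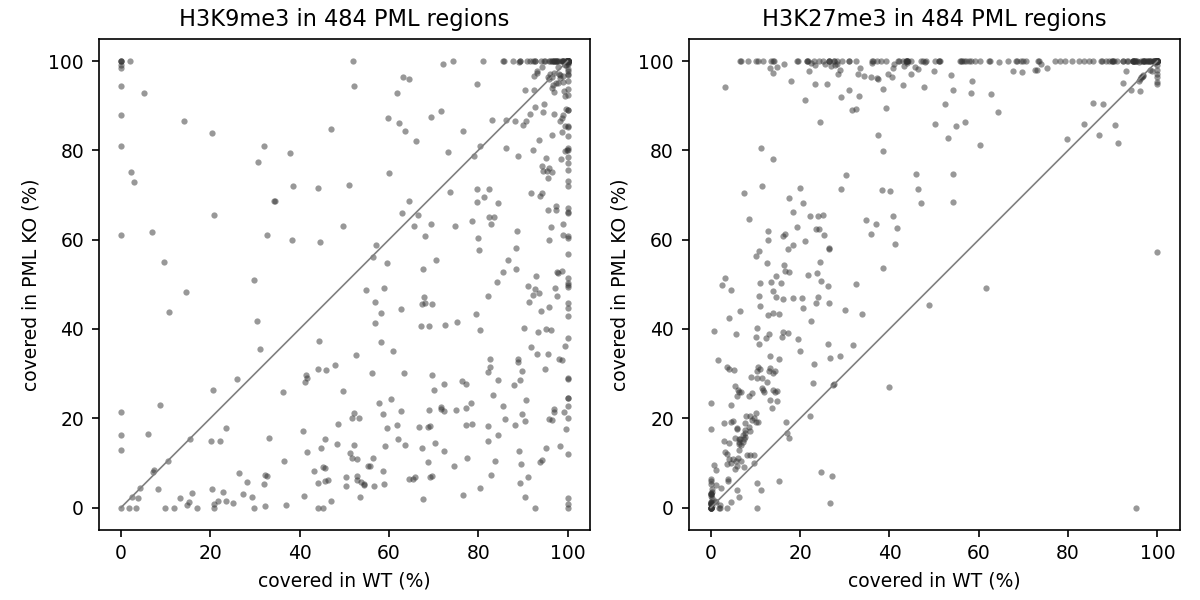
Percent of each of the 484 WT PML regions covered in WT (horizontal axis) and in KO (vertical axis), for H3K9me3 and for H3K27me3, with the line of equal cover. Over calls of any signal, H3K9me3 lay below the line in 329 regions and H3K27me3 above it in 399.

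The inside minus outside difference was 1.07 for H3.3-Flag and 3.38 for H3.3-HA, from near absence inside, and -1.003 for H3. All 5 marks had an adjusted p of 0.0001 by rotation, the smallest possible. Among single regions, H3.3-Flag covered more in KO in 107, less in 97 and the same share in 280. With a minimum signal of 3 the H3.3-HA difference was 2.26, from 1.17 inside and -1.09 outside, and KO cover inside was 0.584%. With a minimum signal of 3, the H3K9me3 ratio turned to 0.69 inside and was 1.61 outside, a difference of -0.93, and with a minimum of 1 it was -0.34 inside and 0.58 outside. With the 300 Mb of highest signal kept in each library, H3K9me3 covered 26.6% of PML regions in WT and 17.3% in KO.

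Bases with H3K9me3 in WT were compared with the marks they carried in KO. Of the bases with H3K9me3 alone in WT, 45.3% inside PML regions carried H3K27me3 in KO, against 25.6% outside and 38.2% (SD 2.23) in rotations, with an adjusted p of 0.00238. Leaving out bases called in the H3 libraries gave 32.6%, against 30.7% in rotations, with an adjusted p of 0.306. H3K9me3 was kept on 55.5% of bases inside, against 53.4% outside (permutation test by rotation, adjusted p = 0.765). H3K27me3 was kept on 94.6% inside and 76.2% outside. Bases with H3K27me3 alone in WT carried H3K9me3 in KO on 56.5% inside and 33.4% outside, and bases with neither mark in WT gained H3K27me3 on 19.9% inside and 7.12% outside, each with an adjusted p of 0.000167.

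Pml RNA was lower in KO in both pairs of tables but was still present. Pml had an FPKM of 15.0 in WT and 10.2 in KO in the numbered tables (difference -0.52), and 7.62 and 4.22 in the unnumbered tables (-0.72). The deleted part of the gene was not given in the sources used, so these levels do not by themselves check the labels. All 19 measured members of the list of PML body and H3.3 chaperone genes differed by less than 2-fold in the numbered pair, and all 18 in the unnumbered pair. Among them Daxx, an H3.3 chaperone, had differences of 0.09 and 0.00, and its partner Atrx 0.54 and 0.11. Hira, which deposits H3.3 at active genes, had 0.13 and -0.28, and the H3.3 gene H3f3b 0.07 and -0.43. The list medians were 0.17 (percentile 83.6) and -0.06 (percentile 18.8).

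In the numbered pair, 719 genes were at least 2-fold higher and 1737 at least 2-fold lower in KO, of 11055. The connexin gene Gjb2 led those higher in both pairs, at 1.31 in WT and 60.8 in KO (difference 4.74). Nrn1 (3.26), the cytokine gene Il11 (2.70), the keratin gene Krt19 (2.17), Pcdh1 (2.14), the activin subunit gene Inhba (1.45), Nipal1 (1.45), the cyclooxygenase gene Ptgs2 (1.43) and the hyaluronan synthase gene Has2 (1.38) followed. The lowest were Nnmt at 112 in WT and 2.05 in KO (-5.21), which lies in a PML region, Clec11a (-4.11), Fndc1 (-3.98), the procollagen protease gene Adamts2 (-3.90) and the troponin gene Tnnt2 (-3.87). Naprt1 (-3.55), Wfdc18 (-3.52), Kazald1 (-3.47) and the Wnt antagonist gene Sfrp1 (-3.40) came next. Ribosomal protein genes took 33.3% of the WT FPKM and 16.5% of the KO FPKM. The fifth of genes with the shortest bodies had a median of -0.40 against 0.20 in the longest. Summed FPKM was 964437 in WT and 417175 in KO, while the median difference over genes was 0.06. The excess of lower genes was not separated from these differences between the tables. The higher count went to 1086 with a pseudocount of 0.1 and to 409 with a minimum FPKM of 5.

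In the unnumbered pair, 203 genes were at least 2-fold higher and 448 lower, of 11687. Genes higher here, and in the other pair, included the chemokine gene Ppbp (2.41), the tubulin-binding gene Stmn2 (2.38), Gjb2 (2.36), Inhba (2.14), Parm1 (1.76), Has2 (1.57), Tspan2 (1.54), A730098P11Rik (1.54) and Gm2115 (1.53). Genes lower included Snhg9 (-3.83), the matrix proteoglycan genes Dcn (-3.60) and Lum (-3.31), Nov (-3.48), Clec11a (-3.46), the immediate-early genes Fos (-3.20) and Fosb (-3.02), Nnmt (-2.98), Hist1h4j (-2.89) and Mgp (-2.74). Dcn had an FPKM of 126 in WT and 9.46 in KO, and Fos 440 and 47.1. Macrophage markers were present in WT, where Tyrobp had 18.1 FPKM and was listed at 0 in KO, and C1qb had 15.2 against 0.235. The lower count was 708 with a pseudocount of 0.1 and 290 with a minimum FPKM of 5.

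The pairs of tables shared few differences, in all 5 gene subsets that were computed. Across 12071 genes the differences had a Pearson correlation of 0.01 and a Spearman correlation of 0.03, and genes are not independent replicates. At least 2-fold differences were shared upward by 27 genes, where independent sets would share 12.1, and downward by 85 against 64.5. Opposite differences were found in 112 genes against 55.9. The numbered and unnumbered WT tables correlated at 0.809 on log2(FPKM + 1), below the 0.953 between WT and KO of the unnumbered pair. Sex-linked genes differed within the numbered pair, where Xist had 19.5 FPKM in WT and 0.0517 in KO while Ddx3y on Y had 0.0384 and 7.67. In the unnumbered pair both tables held both, with Xist at 5.89 in WT and 8.25 in KO and Ddx3y at 21.7 and 11.4. Genotype thus went together with the sex of the cells in the numbered pair, and their effects on RNA cannot be told apart there.

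Interferon-stimulated genes, the antiviral response, stood at opposite ends in the 2 pairs. In the numbered pair 21 of 23 were at least 2-fold higher in KO, with a median of 2.22 (percentile 100), Cxcl10 from 0.299 to 31.7, Usp18 from 0.152 to 14.4 and Ifit1 from 0.492 to 17.6. In the unnumbered pair 9 of 21 were at least 2-fold lower, with a median of -0.92 (percentile 0), Ifit3 from 4.29 to 0.288 and Psmb8 from 5.45 to 0.849. In that pair macrophage markers were lower as well, 12 of 13 by at least 2-fold with a median of -2.02 (percentile 0). Secretory genes of senescence had medians of 0.65 (percentile 99.8) and -0.72 (percentile 0), with Igfbp4 at 1.74 and -1.65. Of the 10 measured in the numbered pair 2 were at least 2-fold higher and 3 lower, and without the expression filter the median was 0.06 (percentile 74.3). Ribosomal protein genes were lower in both, with medians of -1.73 and -0.28 (percentile 0 each), and Rplp2 at -4.22 and -0.16. Replication histone genes were also lower in both, at -0.66 and -0.86 (percentile 0 each), with Hist1h1c at -2.73 and -0.54. Of 60 such genes 38 were measured in the numbered pair and 53 in the unnumbered pair, so the medians were not over the same genes. Whether both pairs captured these RNAs alike was not tested. The numbered histone median was -0.06 without the filter, -1.07 with a pseudocount of 0.1 and -2.18 with a minimum FPKM of 5. In the same tables the fifth of genes with the shortest bodies had a median of -0.40.

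Fibroblast matrix genes had 9 of 23 at least 2-fold lower in the numbered pair (median -0.83, percentile 13.2) and 7 of 24 in the unnumbered (median -0.26, percentile 0), among them Dcn and Lum, while S100a4 had -3.12 and 1.31. Pdgfra, a receptor gene in a PML region, had 1.87 and -2.85. Contractile genes had medians of -1.13 (percentile 15.9) and 0.76 (percentile 100), with Myl9 at -2.64 and 0.93. Genes of oxidative phosphorylation had -0.89 (percentile 14.4) and 0.06 (percentile 44.2), with Ndufa2 at -3.87 and 0.32. Cell cycle genes had 0.03 (percentile 81.8) and -0.30 (percentile 0.01), with Mcm6 at -0.46 and -1.13. Genes for H3K9 methylation and HP1 had 0.37 (percentile 97.7) and -0.06 (percentile 13.0), with the methyltransferase genes Setdb1 at 1.22 and -0.15 and Suv39h2 at 1.04 and -0.17. The numbered value lay within random lists with a pseudocount of 0.1 (percentile 97.4), without the filter (97.2) and with a minimum FPKM of 5 (94.0). Polycomb genes had 0.18 (percentile 72.9) and -0.03 (percentile 36.3), and p53 targets 0.16 (percentile 76.6) and -0.07 (percentile 5.95).

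Hox genes, which record position along the embryo, had signed medians within random lists at 0.29 (percentile 84.3) and -0.18 (percentile 2.56), but differed in both directions. Their median absolute difference in the numbered pair was 1.07, above the 0.70 that bounds random lists, with 7 higher and 5 lower by at least 2-fold. In the unnumbered pair it was 0.46, above a bound of 0.37, with 0 at 2-fold. Hoxc10 went from 0.323 in WT to 41.3 in KO, Hoxa10 from 0.140 to 20.2, Hoxb9 from 0.574 to 26.7 and Hoxc9 from 0.0737 to 13.2. Imprinted genes had medians of 0.25 (percentile 87.1) and -0.18 (percentile 1.75), with Dlk1 at 5.42 and -1.99 and Igf2 at 4.93 and -0.07. With a minimum FPKM of 5 the numbered medians lay above random lists for Hox genes (0.59, percentile 98.5) and imprinted genes (0.70, percentile 100). Sex-linked markers had 1.42 (percentile 99.6) and -0.88 (percentile 0.09).

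**Figure D3:**
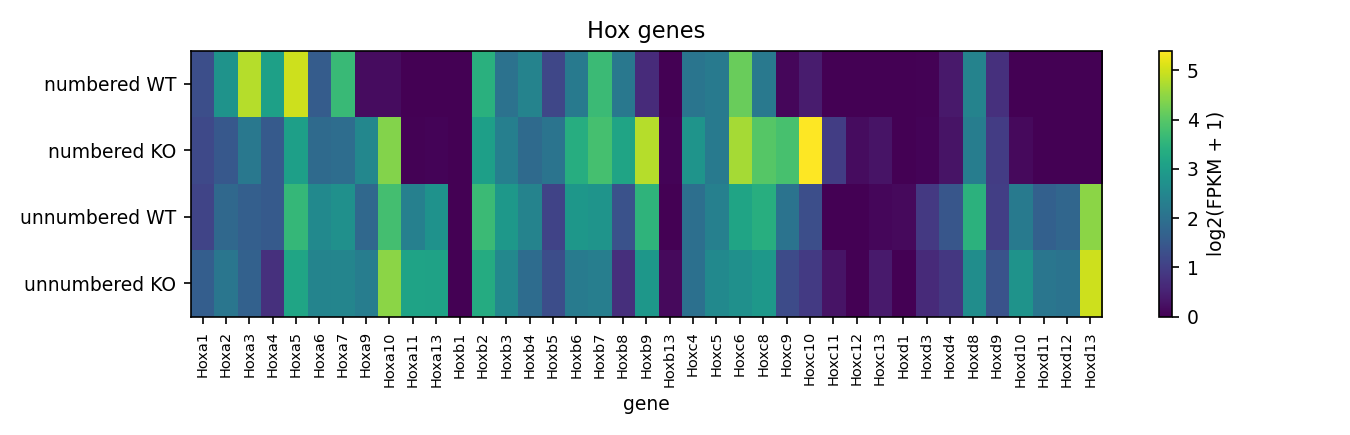
Expression of 39 Hox genes (columns) in the 4 RNA tables, as log2(FPKM + 1) by colour, 1 table per line. Hoxc10 had an FPKM of 0.323 in the numbered WT table and 41.3 in the numbered KO table.

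**Figure D4:**
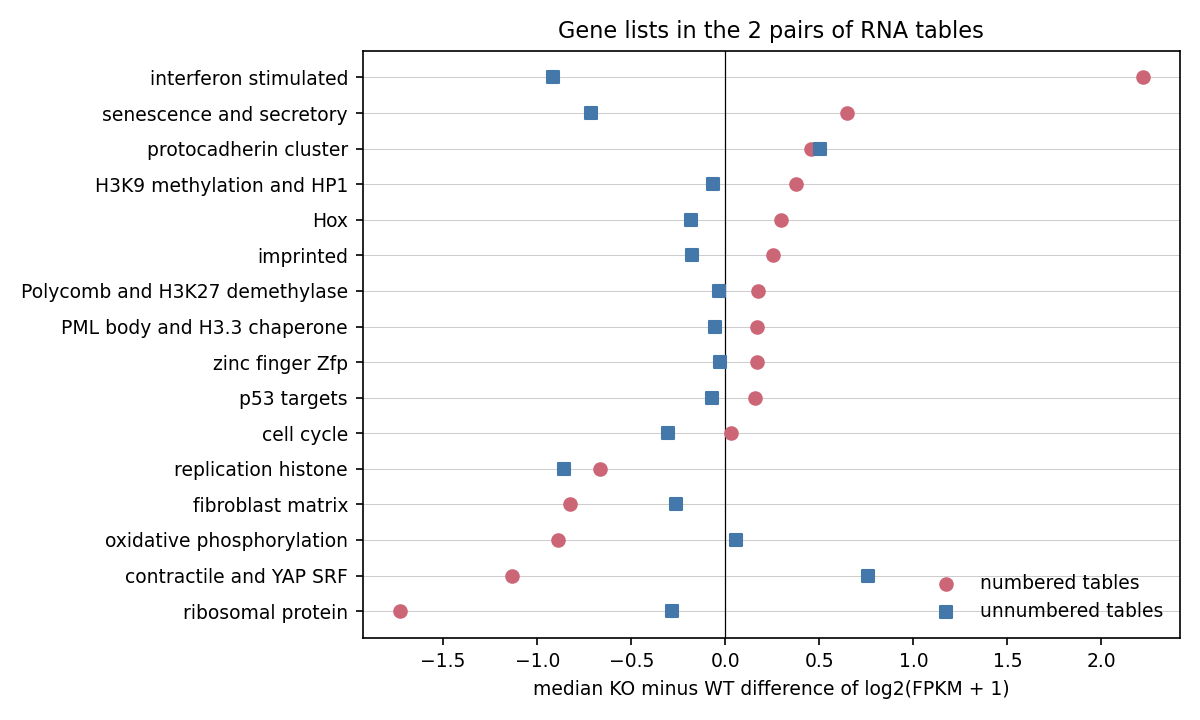
Median KO minus WT difference of log2(FPKM + 1) (horizontal axis) for the gene lists with at least 7 measured members in both pairs, in the numbered tables (red circles) and the unnumbered tables (blue squares). Interferon-stimulated genes stood at 2.22 and -0.92, and ribosomal protein genes at -1.73 and -0.28.

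Further lists covered markers of other cell types and gene families, most with few measured members. Endothelial markers had medians of -1.62 (percentile 0.5) and -0.57 (percentile 6.31) over 3 genes in each pair that were not the same, with Egfl7 at -2.19 and -0.57. Skeletal muscle markers had -1.16 (percentile 0.88) and 0.12 (percentile 71.4), adipocyte markers -0.60 (percentile 5.89) and -0.51 (percentile 5.08), and cartilage and bone markers -0.33 (percentile 40.1) and 0.07 (percentile 65.9). Defensin and serpin genes had -1.37 (percentile 0.175) and 0.27 (percentile 97.2), with Serpinb9b at -4.22 and 0.27. The numbered skeletal muscle value lay within random lists without the filter (percentile 38.9) and with a minimum FPKM of 5 (percentile 10.7), and that of defensin and serpin genes without the filter (percentile 50.0). Keratin genes had 1.2003 (percentile 96.4) and 1.25 (percentile 99.9), over 3 measured genes in each pair that were not the same. Krt19 was at least 2-fold higher in both, Krt80 in the numbered pair only and Krt7 in the unnumbered pair only. Clustered protocadherin genes had 0.46 (percentile 81.6) and 0.51 (percentile 99.7). The Zfp zinc finger genes, with 250 and 281 measured members, had 0.17 (percentile 60.1) and -0.03 (percentile 57.5). Epithelial, neural, germline, olfactory and vomeronasal lists had fewer than 3 measured members, among them Krt19, Ncam1 (1.02 and 0.06) and Map2 (-0.91 and 1.42). Numbered medians also moved with the settings. With a pseudocount of 0.1 they were 3.39 for interferon-stimulated, 4.11 for sex-linked, -2.48 for endothelial, 2.21 for keratin and -2.33 for defensin and serpin genes. Without the filter they were 0.06 for Hox, 0.07 for imprinted, -0.02 for endothelial, 0.08 for protocadherin and 0.06 for Zfp genes (percentile 20.9), and 0 for keratin, skeletal muscle, adipocyte, cartilage and bone, and defensin and serpin genes. With a minimum FPKM of 5 they were 3.06 for sex-linked and -2.78 for defensin and serpin genes.

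Genes in PML regions were almost all silent, and the few expressed ones showed no shared direction. Of 2394 genes with RNA values inside, 2.30% had an FPKM of at least 1 in WT, against 51.3% of other genes and 45.1% in rotations (percentile 0). The 70 measured genes had a median of 0.17 (percentile 82.9 among rotations of membership, 50.8 among matched lists), with 12 at least 2-fold higher and 12 lower. In the unnumbered pair the 105 measured genes had a median of -0.02 (percentile 20.9). Nnmt, on chromosome 9 from 48538002 to 48607655, and Ctla2a, on chromosome 13 from 60934155 to 60936625, were the genes at least 2-fold lower in both pairs, Ctla2a at -3.35 and -1.66 and singled out after its values were seen.

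Genes that lost or gained a mark in KO were compared in the same way. Neither the rotation of membership nor the matched lists controlled gene length, and the lengths of the genes in these sets were not compared. In the numbered pair the fifth of genes with the shortest bodies had a median of -0.40 against 0.20 in the longest. In the unnumbered pair these were -0.06 and 0.02. Small shifts below may therefore reflect gene length. Genes losing H3K27me3 had a median of -0.14 in the numbered pair (311 measured, percentile 0.03) and -0.22 in the unnumbered pair (376, percentile 0). Without bases of the H3 libraries the numbered median was 0.04 (percentile 3.92, but 0.79 among matched lists). Genes losing H3.3-Flag had -0.14 (400 measured, percentile 0.01) and -0.04 (409, percentile 1.70). Genes gaining H3.3-Flag had -0.06 (427, percentile 2.41, but 3.71 among matched lists) and 0.09 (439, percentile 100). Outside H3 calls their numbered value was 0.13 (percentile 84.2). Genes losing H3K9me3 had 0.13 (138, percentile 85.2) and -0.11 (167, percentile 0.02), and those gaining H3K27me3 had 0.12 (130, percentile 49.5) and -0.11 (162, percentile 0). Genes gaining H3K9me3 had 0.03 (percentile 0.83) and 0.02 (percentile 17.2, but 97.9 among matched lists), and outside H3 calls the numbered value was 0.16 (percentile 64.6). Genes gaining or losing H3.3-HA had -0.13 and -0.26 in the numbered pair (percentile 0 each). In the unnumbered pair they had 0.02 (percentile 99.96, but 97.1 among matched lists) and -0.01 (percentile 13.0, but 0.93 among matched lists). Gains outside H3 calls had -0.02 (percentile 6.10) in the numbered pair. Genes gaining H3 had -0.19 (2161 measured, percentile 0) and 0.01 (2247, percentile 54.1), and those losing H3 0.10 (239, percentile 34.5) and 0.01 (263, percentile 53.8).

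H3K9me3 cover differed by chromosome, and chromosome 5 stood apart from the remaining autosomes. There, over calls of any signal, H3K9me3 covered 36.2 percentage points more in KO, where the other autosomes ranged from -26.5 to 13.3. H3K27me3 covered 17.5 points more, against -6.89 to 6.38, and H3 18.6 points more, against -6.85 to 13.0. H3.3-Flag covered 1.49 points more, inside the range of -0.828 to 1.84. On X, H3K27me3 covered 21.5 points more. With a minimum signal of 3, H3K9me3 covered 57.5 points more of chromosome 5 in KO. The other autosomes then ranged from 0.812 to 29.3, so their negative H3K9me3 differences depended on faint calls. Chromosome 5 was singled out after its values were seen.

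**Figure D5:**
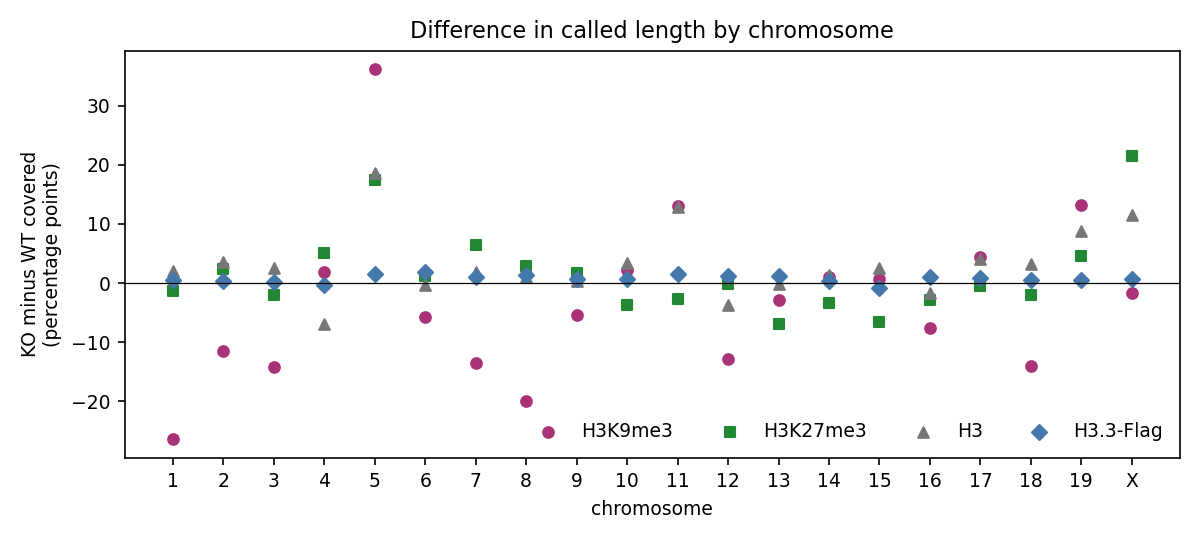
KO minus WT difference in the percent of each chromosome covered by called regions (vertical axis, percentage points) for H3K9me3, H3K27me3, H3 and H3.3-Flag, 1 pair of libraries per mark. Over calls of any signal, chromosome 5 had the highest H3K9me3 difference, 36.2 points.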

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

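All tests in this part were chosen after the results had been seen. Several gene lists pointed in opposite directions in the numbered and unnumbered tables, and the difference between pairs was itself not tested. Interferon-stimulated genes had a median difference of 2.22 in the numbered pair and -0.92 in the unnumbered pair. Secretory genes of senescence had 0.65 and -0.72, and sex-linked markers 1.42 and -0.88. The sex-linked value of the numbered pair set WT cells with Xist against KO cells with Y genes. Genotype and sex of the cells cannot be told apart in that pair.

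The opposite directions were part of a wider lack of relation between the differences of the 2 pairs. Sex-linked genes were not the whole cause, since over autosomal genes alone the correlation was 0.0151. A trend with gene length in the numbered tables was not either, since removing it left -0.0108. The autosomal comparison kept 11625 of 12071 genes, so it changed the gene set little. It cannot address the different sex of the numbered WT and KO cells, which was not tested as a cause. Cultures of different embryonic position or make-up may have contributed, as the higher of the correlations over Hox genes between tables of the same genotype was 0.189, while WT and KO correlated at 0.863 in the unnumbered pair and at 0.352 in the numbered pair. An effect of PML loss that depends on the culture stays open and was not tested.

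Long calls appeared in parts of the genome left out of the covered lengths and the rotations, but not of the region counts. On Y, 90.8 Mb were called for H3K9me3 in WT, 90.7 Mb for H3.3-HA in KO and 84.2 Mb for PML in KO. In the first 3 Mb of chromosomes 1 to 9, 27 Mb were called for H3K9me3 in WT, 24 Mb for H3K27me3 in WT, 21 Mb for H3K27me3 in KO and 12 Mb for H3.3-HA in KO, while the other libraries had 0.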

How the results depend on the processing

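Alternatives gave 408 values beside the main ones, 318 of them planned and 90 added after the data had been seen, and 314 were unchanged. Unchanged meant the same direction and side of the threshold for a test, within the 95% interval of the main value for a share, within 1.5 times for a count or length ratio, and within 1 SD of random lists for a list median. By this rule a list can leave or enter the outside of random lists and still count as unchanged. All 29 values for the change inside PML regions did, between -0.93 and -0.36 for H3K9me3 and between 1.01 and 1.37 for H3K27me3, as did 56 of 58 for overlap with PML regions and 28 of 30 for exchange. No paired analysis was possible because the replicate numbers match between genotypes but the tables hold 1 pooled value per genotype. For the same reason leaving out each replicate and a replicate block were not run. Assignment by transcription start was not run because the annotation used gives no strand, and the midpoint took its place. Bases outside H3 calls gave no value for H3 itself. A signal minimum gave no length ratio or touched share for H3 and PML, whose calls carry no signal. In the overlap and change tests it left H3 as it was, so those H3 values were counted as unchanged although they could not move. Overlap of H3.3-Flag in WT could not move either, as its lowest signal was 12.1. For the values below the cause was not tested.

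The share of WT regions touched in KO moved with the choice of regions. At the minimum length it was 77.3% for H3.3-Flag, 52.97% for H3.3-HA, 54.4% for H3K9me3 and 4.92% for PML. In the upper part of the score it was 70.2%, 44.3%, 44.1%, 72.0% for H3K27me3, 71.6% for H3 and 1.24% for PML, where the length ratio of PML was 0.0214. The stricter overlap gave 72.7% for H3.3-Flag. Autosomes gave 46.9% for H3K9me3 and 68.3% for H3K27me3. Chromosomes 10 to 19 gave 52.0% for H3.3-HA, 43.7% for H3K9me3 and 60.3% for H3K27me3. A minimum signal of 1 gave 22.7%, 47.5% and 65.1% for these, and a minimum of 3 gave 8.42%, 44.7% and 57.0%, and 72.6% for H3.3-Flag. The length ratio of H3.3-HA was 2.09 at a minimum of 1 and reversed to 0.504 at 3, and that of H3K9me3 was 2.39 at 3.

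Overlap of H3.3-HA in KO with PML regions passed the threshold at a minimum signal of 3 (0.449 of the rotations), and that of H3 in KO no longer did on chromosomes 10 to 19 (0.978). H3K9me3 bases with H3K27me3 in KO fell within rotations outside H3 calls (32.6%), and kept H3K9me3 passed at a minimum signal of 3 (72.3%).

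Genes higher in KO in the numbered pair numbered 1086 with a pseudocount of 0.1, 409 with a minimum FPKM of 5 and 203 in the unnumbered tables, where 448 were lower. In the unnumbered pair 347 were higher and 708 lower with a pseudocount of 0.1, and 290 lower with a minimum FPKM of 5. A median is called reversed when it lay outside random lists or rotations in the numbered pair and took the other sign, or for gene sets the other side of the rotations. With the unnumbered tables this held for H3K9 methylation (-0.0644), interferon-stimulated (-0.92), senescence (-0.72), skeletal muscle (0.12), sex-linked (-0.88) and defensin and serpin genes (0.27), and for genes gaining H3.3-Flag (0.0943), H3.3-HA (0.0248) and H3 (0.0119). Outside H3 calls it held for genes gaining H3K9me3 (0.16) and H3.3-Flag (0.13). Medians not outside in the numbered pair also took the other sign, among them contractile (0.76), cell cycle (-0.30), Hox (-0.18) and imprinted genes (-0.18), genes losing H3K9me3 (-0.11) and genes gaining H3K27me3 (-0.11). The unknown depth limits how far a listing at 0 or an uncalled region can be read.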

Other observations

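In this part, the tests were chosen after the results had been seen, except that of chromosome 5 at high signal and that at equal covered length. The latter was set before its own result but after the related result at a signal minimum of 3 was known. H3K9me3 cover, over calls of any signal, differed between genotypes over some clustered gene families. This cover was not computed at a signal minimum, although 534.1 of the 840.6 Mb in WT lay below a signal of 3. The 367 Zfp zinc finger genes had 44.95% of their length in H3K9me3 in WT and 45.00% in KO, although 269 were touched in WT and 235 in KO. Over olfactory receptor genes H3K9me3 covered 61.6% of the length in WT and 19.9% in KO, and H3K27me3 26.95% and 38.3%. Over vomeronasal receptor genes H3K9me3 covered 68.4% and 25.7%, and H3K27me3 11.5% and 37.0%. Clustered protocadherin genes had 75.1% and 43.2% H3K9me3. Keratin genes went the other way, with 4.12% in WT and 46.5% in KO, and Hox genes had 17.5% and 54.1% while their H3K27me3 stayed at 73.7% and 72.6%. H3 calls covered 75.0% of keratin gene length in WT and 69.6% in KO, and 21.2% and 39.8% of Hox gene length. The H3K9me3 cover of these families was not computed outside H3 calls, so a gain apart from H3 was not shown.

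H3.3 and the repressive marks followed expression in opposite ways. In the numbered WT table H3.3-Flag touched 20.5% of genes listed at 0 and 89.2% of genes with an FPKM of at least 100. H3K27me3 covered on average 57.9% of the length of genes listed at 0 and 4.49% at the top, and H3K9me3 36.5% and 3.76%. All 23 interferon-stimulated genes located were touched by H3.3-Flag in both genotypes, over 100% of their length in WT and 99.7% in KO, although their RNA differed in opposite directions between the pairs of tables. H3.3-HA covered 80.6% of their length in WT and 29.9% in KO.

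Hox expression set the pairs of tables apart. Hoxd13, which marks distal limb and tail, was listed at 0 in both numbered tables and had an FPKM of 20.9 in the unnumbered WT table and 30.96 in the unnumbered KO table. The imprinted gene H19 had 0.673 in the numbered WT table and 1708 in the unnumbered WT table. These genes were singled out after their values were seen.

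Faint WT calls could account for the lower H3K9me3 length in PML regions in KO, since with a minimum signal of 3 the log2 ratio inside was 0.69. This stays open, because at equal covered length PML regions still had 26.6% in WT and 17.3% in KO. Relative to the remaining genome the log2 difference stayed at -0.93 at a minimum of 3. In percent cover no deficit was seen there, with a rise from 27.4% to 44.1% inside and from 8.03% to 24.6% outside. At that minimum H3K9me3 was kept in KO on 72.3% of its WT bases inside and 53.7% outside. Whether faint calls account for the relative deficit therefore depends on the measure and stays open. Unequal covered length did not account for it, since with the 300 Mb of highest signal in each library the log2 difference was -1.01. There cover outside PML regions was 7.83% in WT and 10.2% in KO. The cut lay at a signal of 3.03 in WT and 7.64 in KO. As read depth was unknown, unequal calling depth itself could not be tested. A loss of H3K9me3 that follows from the loss of PML stays open as a hypothesis, with 1 library per genotype.

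The excess of called H3K9me3, H3K27me3 and H3 on chromosome 5 in KO could come from an extra copy in the cultures used for ChIP, which was not tested. An extra copy in the cells used for RNA would shift the median of its genes by about 0.585, and the unnumbered pair had 0.0466. For H3K9me3, the mark tested, the KO calls there were not of low signal, as they covered 77.4% of chromosome 5 with and without a minimum of 3. At that minimum chromosome 5 had 57.5 points more H3K9me3 in KO and the other autosomes between 0.812 and 29.3 points more. That comparison decides little, since the minimum removed 534.1 Mb of WT calls and only 1.91 Mb of KO calls.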
